A study of Mus musculus with 136 samples.

How the data were processed

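RNA-seq was deposited for 70 samples, ATAC-seq (a map of open chromatin) for 18, and chromatin immunoprecipitation of H3K27ac, H3K4me1 and H3K4me3 for 12 each, with 12 input samples, 136 in all. The input samples came with no peak list of their own and served here in no comparison of their own. Each sample was placed in its group by its label, and 0 columns of the tables were left unmatched.

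The RNA tables hold RPKM per RefSeq transcript, computed and deposited by the authors. Per the submitters' processing notes the tools were Bowtie 1.1.1, TopHat2 2.1.0 and Partek 6.6 with build mm9, but the notes do not say which tool made which value. The first table held 16 libraries of cells sorted from lung and 34993 transcripts, the second 6 libraries of Rara cultures and 36416 transcripts, and the third 48 libraries of OT-II cultures and 34973 transcripts. RPKM values were summed over the transcripts of each gene symbol as the tables give it, which left 20641, 24189 and 23906 genes. Reads shared between transcripts of a gene may be counted more than once in such a sum. In the lung table, 64 gene symbols that a spreadsheet had turned into dates were restored from their transcript accessions. Per the labels' protocols some libraries came from a strand-specific kit and others from another kit, so overlapping and antisense genes, and near-identical family members such as Tmem176a and Tmem176b, are uncertain. Counts of reads per RNA library were not given in the sources used here. A search for whole-read steps among genes with low values found that the commonest ratio between libraries was shared by at most 4.8% of 1391 such genes in the lung table, 13.2% of 5232 in the Rara table and 10.7% of 4499 in the OT-II table, so read depth was left unknown.

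Peaks were called with MACS 1.4.2, per the file headers of all 54 peak lists, at a p-value cutoff of 1e-05 and a band width of 300. Per the file headers each list gives for each peak the count of tags in it, a score of -10 times the log10 of the p-value, and a fold enrichment, a ratio over the caller's background model. The headers name a control library for the histone marks and none for ATAC-seq. They also show that wild-type ATAC libraries were called with a fragment length of 78 to 84 and gave peaks with a median length of 233 to 310 bp, whereas the Rara ATAC libraries were called with 200 and gave peaks of 1125 to 1454 bp. Regions are mm9 positions counted from 1. The reference annotation used here is of another assembly, GRCm38, and served only for gene names, so no region was assigned to a gene.

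Genes were tested in R 4.3.3 with limma 3.58.1 on log2(RPKM + 1), with eBayes and a trend on mean expression, 1 linear model per table. A gene was tested when it reached an RPKM of 1 in at least as many libraries as the smallest group holds, which left 12408 genes in the lung table, 10396 in the Rara table and 12320 in the OT-II table. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called at 0.05. Log2 differences are of RPKM + 1 and therefore shrink toward 0 for genes near 0. Values are given as mean ± SD of RPKM with the number of libraries as n, and errors of log2 differences as SE. All limma tests were two-sided. The labels do not say whether replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. Each gene's spread is pooled over all groups of its table, so a p-value does not measure the spread of the compared groups alone.

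Gene lists were tested with camera of limma at a preset correlation of 0.01 and, as an alternative, with a correlation estimated from the data, adjusted over the lists. The 25 lists were fixed before the data were examined, as were the groups, the comparisons, the rule for named genes and the alternatives. They were the Th9, Th2, Th1, Th17 and Treg programs, the retinoic acid response, homing receptors, TGF-beta signalling, cytokine receptors, STAT and SOCS genes, TNF receptor family costimulation, inhibitory receptors, cell cycle, glycolysis, cholesterol synthesis, interferon response, immediate early and stress genes, naive and memory T cell genes, and markers of B cells, myeloid cells, granulocytes and mast cells, CD8 and NK cells, group 2 innate lymphoid cells (ILC2), lung stroma and erythroid cells.

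Genes were named in the text by a rule. Always named were 17 genes: Il9, Il4, Il5, Il13, Il17a, Ifng, Foxp3, Rara, Irf4, Batf, Spi1, Gata3, Il10, Ccr9, Il1rl1, Il17rb and Pparg. Also named could be the 10 genes with the largest increase and the 10 with the largest decrease among called genes with a mean of at least 5 RPKM in the higher group, unnamed gene models left out, and up to 4 members of each list with the largest change. Secondary comparisons used the 17 genes and up to 2 members of each list.

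For chromatin, overlapping peaks of the libraries compared were merged into regions. A region was gained when every library of 1 group and none of the other had a peak in it, and lost in the reverse case. Regions gained or lost with retinoic acid in wild-type Th9 cultures were also scored, as a held-out set, in the floxed and Rara knockout cultures, and held-out gene sets needed a log2 difference of at least 1. Whether replicate numbers pair libraries was read from correlations across genes of the libraries' deviations from their group. Equal numbers paired the Rara RNA libraries and the lung Th9 libraries with Th2 and with Th1, and marked a sequencing run in the Th17 cultures. In the lung YFP-positive and YFP-negative groups replicate 1 came from another run than replicates 2 and 3, so the pairing there partly reflects the run. A fit with replicate number as a block is given beside a result only for those comparisons, and there only where it changed a call or moved a count by over 1.5 times.

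The fits were tested on simulated data drawn from the real means and spreads. For retinoic acid in Th9 cultures (12320 genes), 76% of genes changed by log2 1 and 99% of those changed by log2 2 were recovered, and 6.53% of calls were false. The Rara knockout simulation (10396 genes) recovered 40% and 96% with 4.73% false calls. Sorted Th9 against Th2 cells (12408 genes) gave 36% and 87% with 4.44% false, and GFP-positive against GFP-negative cells (12408 genes) gave 6% and 66% with 2.6% false. In each simulation the shifted list of 15 genes was called and 0 of 24 other lists were. Each gene and library was drawn independently, so the simulations hold no correlation between genes and no replicate or run effect. Changed genes came only from those with a mean log2(RPKM + 1) of at least 2. The rates therefore need not hold for the real data, and the list result cannot show how camera behaves with correlated genes. The merging of peaks was tested on 17200 simulated region-library pairs, 0 of which differed from a direct computation, and 100 of 100 planted gained and 50 of 50 planted lost regions were found.

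The alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization between libraries, a block for replicate number, only the libraries compared, each library left out in turn, an overlap of at least 50%, the upper 50% of peaks by score, the same number of top peaks in each library, an estimated correlation in list tests and no fold limit for held-out sets. Chosen after seeing the data were the block together with quantile normalization and the fit without replicate 2 of both groups for the knockout, and the restriction of the lung comparisons to genes present in cultured Th9 cells. Tables and peaks were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.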

Results

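Mouse CD4 T cells were profiled to ask how retinoic acid (RA), the vitamin A metabolite that activates the receptor RARα (gene Rara), acts on Th9 cells, the helper T cells that secrete interleukin 9. Naive cells were activated in culture for 72 h toward Th0 (no polarising cytokine), Th1, Th2, Th9, Th17 or induced regulatory (iTreg) fates. Each fate was set up with vehicle or 1 µM RA. Th9 cultures received 20 ng/mL interleukin 4 with 2.5 ng/mL TGF-beta and interleukin 2, and iTreg cultures 10 ng/mL TGF-beta with interleukin 2. RNA was measured in 2 libraries per subset and treatment from OT-II mice, whose T cells carry 1 transgenic receptor, and from OT-II Scurfy mice, which carry a loss-of-function mutation of Foxp3 (48 libraries). It was also measured in 3 floxed control and 3 Rara knockout Th9 libraries (Rara deleted by Cre under the Cd4 promoter), all with vehicle. A further 16 libraries came from memory-type CD4 T cells sorted from lungs of papain-sensitised mice, a model of airway allergy. They were YFP-positive Th9 cells and YFP-negative Th2, Th1 and Th17 cells (3 each), and GFP-positive Th9 and GFP-negative cells (2 each). Per library, 10219 to 10860 genes reached 1 RPKM in the OT-II cultures, 9980 to 10458 in the Rara cultures and 9799 to 11125 in lung cells. Across genes, replicates correlated at r of 0.954 to 0.992, 0.965 to 0.991 and 0.858 to 0.991. Read depth of the RNA libraries is unknown. Chromatin was profiled in Th9 cultures with and without RA, from wild-type, floxed and Rara knockout mice (2 libraries each), by ATAC-seq, H3K4me1, H3K27ac and H3K4me3, and by ATAC-seq in wild-type Th2 and iTreg cultures. For the histone marks of the Rara cultures the labels name Cre under Cd4 but the names of the peak lists CD2, and the labels were followed. Filtered tags per library ranged from 1.7 M in wild-type ATAC to 42 M in H3K4me1 of the Rara cultures.

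The first question was what RA does to cultured Th9 cells. RA lowered Il9 from 1027 ± 61.9 to 64.4 ± 0.815 RPKM (SD, n = 2 per group; log2 difference -3.97, SE 0.89, adjusted p = 0.00482). Il13, another type 2 cytokine, fell from 12.8 ± 6.71 to 0.787 ± 0.0044 RPKM (log2 -2.86, adjusted p = 0.0223). Il12a, a subunit of interleukin 12 and 35, fell from 32.5 ± 7.59 to 0.973 ± 0.131 RPKM (log2 -4.07). Foxp3, the regulatory T cell factor, rose from 11.6 ± 2.44 to 65.5 ± 2.49 RPKM (log2 2.41, SE 0.53, adjusted p = 0.00378). The gut-homing receptor Ccr9 rose from 0.0908 ± 0.0302 to 18.4 ± 1.78 RPKM (log2 4.15, SE 0.34, adjusted p = 3.02e-09). The transcription factor Maf rose from 6.92 ± 0.933 to 50.7 ± 2.59 RPKM (log2 2.71). The unpaired test pools each gene's spread over all OT-II cultures, for Il4 including Th0 vehicle libraries at 27 and 0.554 RPKM. Several Th9-associated genes did not pass it. Il4 went from 15.9 ± 2.06 to 0.321 ± 0.108 RPKM (adjusted p = 0.0786) and Gata3 from 83.3 ± 14 to 34.3 ± 7.23 (adjusted p = 0.0621). Neither did Batf (69 ± 17.6 to 33.8 ± 1.28, adjusted p = 0.0628, or 0.0437 with quantile normalization), Il10 (adjusted p = 0.118) and Irf4 (adjusted p = 0.639). Il5, Ifng, Il17a, Pparg and Rara (18.1 ± 0.597 to 11.4 ± 0.178 RPKM, adjusted p = 0.177) also stayed above the threshold, and Spi1 and Il1rl1 were below the expression filter.

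Among other large changes, the neuropeptide galanin (Gal) rose by log2 5.21 to 46.4 ± 18.9 RPKM, and Art2b, an ADP-ribosyltransferase, by log2 4.01. Asb2, a subunit of a ubiquitin ligase, rose by log2 3.99, Rab20, a small GTPase, by log2 3.71 and the imprinted RNA H19 by log2 3.36. The genes with the largest decreases included Lmna, the nuclear lamin A (log2 -4.03), the kinase gene Zak (log2 -3.34) and the neurotrophin receptor Ntrk3 (log2 -3.28). The phospholipase genes Plcd1 (log2 -3.10) and Pla2g4f (log2 -3.07) fell too, as did Kynu, an enzyme of tryptophan breakdown (log2 -3.02), and Pdpn, podoplanin (log2 -2.98).

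Of 14 measured genes of the retinoic acid response list, 6 rose and 1 fell (adjusted over the list alone, 8 and 4). Hic1, a transcriptional repressor, rose by log2 4.69 to 40.4 ± 0.495 RPKM, the retinol-uptake receptor Stra6 by log2 3.39 to 95.7 ± 28.3 RPKM, and Dhrs3, which reduces retinaldehyde, by log2 3.12. Rxra, a partner receptor of RARα, fell by 1.59 on the log2 scale. The list as a whole moved up (median log2 1.58, camera adjusted p = 0.00289; adjusted p = 0.21 with an estimated correlation). Of 15 TGF-beta signalling genes, 3 rose (5 adjusted over the list alone): Smad3, a signal transducer (adjusted p = 0.00044), Smurf1, a ubiquitin ligase (log2 1.02), and the receptor Tgfbr1 (log2 0.87). The list moved up at adjusted p = 0.0338 (adjusted p = 0.49 with an estimated correlation). Of 12 naive and memory genes, 1 rose and 3 fell (2 and 6 adjusted over the list alone), and the list moved down at adjusted p = 0.00141 (adjusted p = 0.143 with an estimated correlation). Among them, Satb1, a chromatin organiser, fell by 1.39. Of 19 cytokine receptors, Il17rb (receptor for interleukin 25) rose by log2 1.69 and Il6ra fell by 1.72, 1 up and 2 down in all (3 adjusted over the list alone). The list moved down at adjusted p = 0.0338 (adjusted p = 0.21 with an estimated correlation). Of 11 costimulatory TNF family genes, Tnfsf11 (RANK ligand) rose by log2 2.45 and Tnfsf8 (CD30 ligand) fell by 2.75, 1 up and 3 down in all (5 adjusted over the list alone). The list again moved down at adjusted p = 0.0338 (adjusted p = 0.49 with an estimated correlation). The 3 measured lung stroma markers moved up at adjusted p = 0.0338 (adjusted p = 0.185 with an estimated correlation), with Epcam called. The 4 erythroid markers moved down at adjusted p = 0.0486 (adjusted p = 0.628 with an estimated correlation), with a median of 0.06 but a mean of -0.44 and Hbb-b2 called.

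No call was made for the Th9 list (15 measured, 2 up and 1 down, 6 adjusted over the list alone, adjusted p = 0.735), Th2 (12, 1 and 1, adjusted p = 0.588), Th1 (17, 1 and 2, adjusted p = 0.588) or Th17 (13, none, adjusted p = 0.736). The Treg list (15, 3 up and 2 down, 8 adjusted over the list alone, adjusted p = 0.588) had a median of -0.35 and a mean of 0.06. Homing receptors (16) had 3 genes up, Ccr9, Itga4 (integrin alpha 4, log2 2.75) and Itgae (CD103, log2 2.88), and 2 down, among them Fut7, which makes selectin ligands (log2 -2.71), at adjusted p = 0.64. Inhibitory receptors (9) had Tigit up (log2 2.14) and 3 down, among them Btla (log2 -2.22), with a median of 0.28, a mean of -0.04 and adjusted p = 0.589. Immediate early genes (16) had 3 up and 1 down (adjusted p = 0.64). With no filter on low values Egr1 (limma adjusted p = 0.053), Egr2 (0.0547), Jun (0.0809) and Dusp1 (0.0595) lost these calls. Cell cycle (20, adjusted p = 0.832), glycolysis (15, 0.431), cholesterol synthesis (16, 0.252), interferon response (18, 0.643), STAT and SOCS genes (12, 0.285) and myeloid markers (9, 0.64) had no called member. B cell (4, 0.285), CD8 and NK (7, 0.832) and ILC2 markers (9, 0.901; median 0.17 against a test direction of down) had 1 each.

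In all, 673 of 12320 genes passed limma (433 up, 240 down). With either arm reduced to 1 library the count was 330 without vehicle replicate 1, 405 without RA replicate 1, 355 without vehicle replicate 2 and 291 without RA replicate 2. Il9 then had an adjusted p of 0.053 without vehicle replicate 2 and 0.0556 without RA replicate 2, and Foxp3 0.068 and 0.0508. Il13 had 0.275 without vehicle replicate 1, 0.122 without RA replicate 1 and 0.143 without RA replicate 2 (and 0.0588 with a pseudocount of 0.1), and Itgae 0.103 without RA replicate 2.

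**Figure D1:**
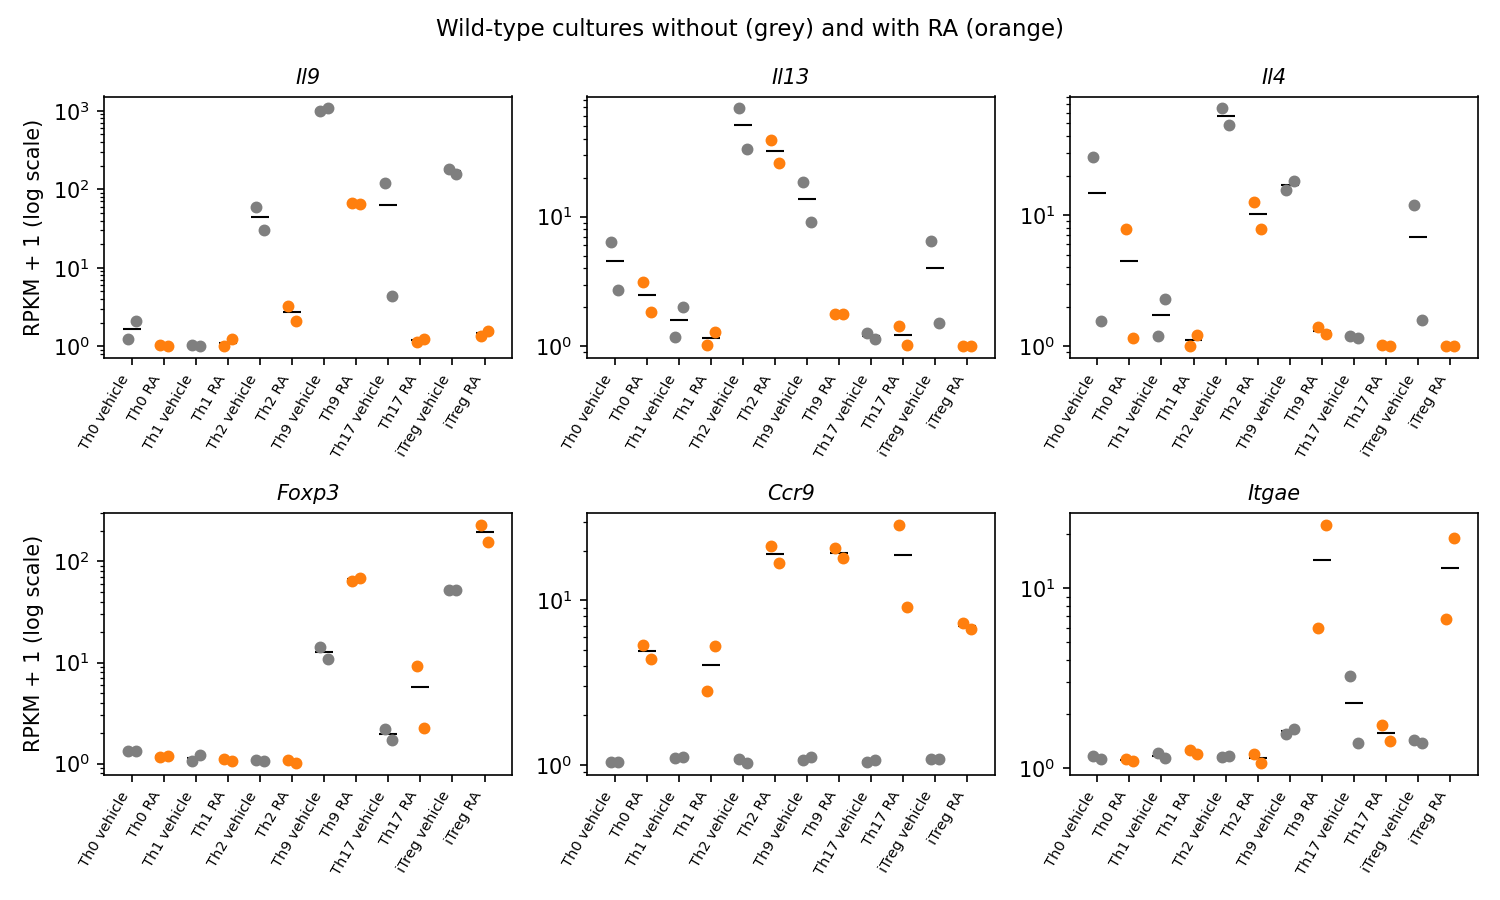
RPKM + 1 (log axis) of 6 genes in 6 wild-type culture subsets with vehicle (grey) or RA (orange); points are libraries and bars are means of 2. Il9 in Th9 cultures stood at a mean of 1027 RPKM with vehicle and 64.4 with RA, and Ccr9 at 0.0908 and 18.4.

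The same treatment in other subsets shows which responses are shared. Ccr9 rose with RA in Th0 (log2 2.22, adjusted p = 0.000339), Th1 (log2 1.80, 0.0055), Th2 (log2 4.16, 4e-09), Th17 (log2 3.94, 8.11e-09) and iTreg cultures (log2 2.69). Il9 fell with RA in iTreg cultures, from 168 ± 15.1 to 0.461 ± 0.157 RPKM (n = 2, adjusted p = 3.91e-06), and in Th2 cultures, from 43.6 ± 20.8 to 1.71 ± 0.823 (adjusted p = 0.0136). In Th17 cultures it fell from 61.7 ± 82.4 to 0.191 RPKM (adjusted p = 0.00339), the vehicle libraries of different runs standing at 120 and 3.4. It did not pass in Th0 (log2 -0.65) or Th1 (log2 0.12), both at an adjusted p of 1. Foxp3 rose in iTreg cultures, from 50.6 ± 0.075 to 193 ± 52.8 RPKM (adjusted p = 0.0237). In Th2 cultures RA raised Il5 from 0.0784 ± 0.0147 to 3.92 ± 0.016 RPKM (adjusted p = 1.5e-10) and Pparg, a nuclear receptor, by log2 1.05. In Th17 cultures it lowered the cytokine genes Il24 (log2 -5.66) and Il10 (log2 -4.34, adjusted p = 0.000867) and raised Nkg7, a gene of cytotoxic granules (log2 3.59). Rara itself fell with RA in Th1 (log2 -1.29, adjusted p = 0.00507), Th2 (log2 -0.95, 0.047) and Th17 cultures (log2 -0.86, 0.0404). The retinoic acid response list moved up in Th0 (adjusted p = 3.13e-09, and 0.0135 with an estimated correlation) and Th2 cultures (2.61e-12, and 0.00278 with an estimated correlation). It also moved up in Th1 (7.82e-05; adjusted p = 0.123 with an estimated correlation) and Th17 cultures (0.00245; adjusted p = 0.325 with an estimated correlation). The Th17 list (adjusted p = 0.00062; adjusted p = 0.325 with an estimated correlation) and cytokine receptors (adjusted p = 1.21e-05, and 0.0083 with an estimated correlation) moved down in Th17 cultures.

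With RA, limma called 113 genes in Th0 (85 up, 28 down), 51 up and 51 down in Th1, 159 in Th2 (110 and 49), 537 in Th17 (325 and 212) and 953 in iTreg cultures (588 and 365). Of the 433 genes raised in Th9 cultures, 255 were also raised in iTreg (20.7 expected by chance), 73 in Th17 (11.4), 51 in Th2 (3.9), 38 in Th0 (3) and 14 in Th1 (1.8). Of the 240 lowered genes, 147 were also lowered in iTreg (7.1 expected), 35 in Th17 (4.1), 35 in Th2 (1), 19 in Th0 (0.5) and 13 in Th1 (1). A test of the Th9 response against the mean response of Th0, Th2 and iTreg cultures called 50 genes (32 up, 18 down). They included Maf (log2 2.32, adjusted p = 2.05e-05) and Tgfbr1 (log2 1.09, adjusted p = 0.000782), whose responses exceeded the mean, whereas Il9 (log2 -0.14, adjusted p = 1) and Foxp3 (log2 1.86, adjusted p = 0.433) were not called. With a pseudocount of 0.1 the count was 20, and it was 25 without Th9 vehicle replicate 1, 28 without Th9 vehicle replicate 2 and 21 without Th9 RA replicate 2. Paired by run, the Th17 cultures gave 1585 genes, and quantile normalization turned their split to 271 up and 302 down. Counts fell by over 1.5 times without single libraries: in Th0 without vehicle replicate 1 (67), vehicle replicate 2 (57) and RA replicate 2 (29), and in Th1 without RA replicate 1 (56) and vehicle replicate 2 (35). They also did so in Th2 without vehicle replicate 1 (101), RA replicate 1 (63) and vehicle replicate 2 (68). The same held in Th17 without RA replicate 1 (168) and in iTreg without vehicle replicate 1 (501), RA replicate 1 (410) and vehicle replicate 2 (440).

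Scurfy cultures address whether the RA response of Th9 cells needs functional Foxp3. RA lowered Il9 in Scurfy Th9 cultures from 643 ± 315 to 62.5 ± 1.31 RPKM (n = 2, log2 -3.25, adjusted p = 0.0372) and Il13 by 2.73 (adjusted p = 0.044). It raised Ccr9 (log2 3.87), Hic1 (log2 3.32), Maf (log2 2.14), Itgae (log2 2.27) and Foxp3 RNA, from 7.91 ± 5.21 to 38.8 ± 35.7 RPKM (log2 1.93, adjusted p = 0.0366). The Foxp3 values with RA were 64 RPKM in replicate 1, near wild type (63.7), and 13.6 in replicate 2. In all, 408 genes changed, 170 of them down. Of the genes raised in wild-type Th9 cultures 229 were also raised (8.4 expected), and of those lowered 167 were also lowered (3.3 expected). The difference between the genotypes' RA responses was called by limma for 0 genes (29 at an unadjusted p under 0.05). Vehicle-treated Scurfy and wild-type cultures differed at 0 genes by limma in Th9 (26 at an unadjusted p under 0.05) and 0 in iTreg cultures (19), with Il9 at 643 ± 315 against 1027 ± 61.9 RPKM in Th9 (adjusted p = 1). Lists were called nonetheless: the retinoic acid response was higher in Scurfy Th9 (adjusted p = 0.00272; adjusted p = 0.606 with an estimated correlation) and the interferon response in Scurfy iTreg cultures (adjusted p = 0.0273; adjusted p = 0.71 with an estimated correlation). In Scurfy Th9 cultures with vehicle some of the retinoic acid genes were high in replicate 2 only: Hic1 at 0.857 and 10.5 RPKM (wild type 1.04 and 0.259) and Stra6 at 8.73 and 40.5 RPKM (wild type 9.66 and 6.65). Ccr9, at low values, stood at 0.0633 and 0.987 RPKM (wild type 0.069 and 0.112). Without vehicle replicate 1 the Scurfy RA count was 123, without RA replicate 1 it was 258 and without RA replicate 2 it was 197.

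Th9 cells were next set against Th2 cells, which share interleukin 4 but not TGF-beta or interleukin 2 in culture. Il9 stood at 1027 ± 61.9 RPKM in Th9 and 43.6 ± 20.8 in Th2 cultures (n = 2, log2 4.61, SE 0.89, adjusted p = 0.00166), and Il12a was higher by log2 4.65. Foxp3 (11.6 ± 2.44 against 0.0772 ± 0.0055 RPKM, log2 3.53, adjusted p = 6.48e-05), the transcription factor Irf8 (130 ± 16.4 against 8.42 ± 1.31, log2 3.80) and Ahr, the aryl hydrocarbon receptor (18.1 ± 2.49 against 1.58 ± 0.656, log2 2.91), were higher in Th9. So were Aqp3, a water and glycerol channel (log2 4.32), and Ctsw, a protease of cytotoxic cells (log2 4.16). Also higher were Sgk1, a salt-sensing kinase (log2 4.06), Adam19 (log2 4.06), Kynu (log2 3.80) and Maf (log2 2.42). Lower in Th9 were Epas1, a hypoxia-inducible factor (log2 -2.99), Lgals7 (log2 -2.75), Filip1l (log2 -2.71), Cst7 (log2 -2.60), Satb1 (log2 -2.17) and Pparg (log2 -2.11, adjusted p = 2.37e-07). Il13 (12.8 ± 6.71 against 49.8 ± 24.9 RPKM, adjusted p = 0.268), Il4 (15.9 ± 2.06 against 55.7 ± 11.8, adjusted p = 0.756), Gata3 (adjusted p = 0.339), Batf (0.213) and Irf4 (1) were not called.

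Of 13 Th17 genes 6 were higher in Th9 (adjusted p = 8.77e-09, and 0.0288 with an estimated correlation), and of 15 Treg genes 4, among them Foxp3 and Ikzf4 (log2 1.75; list adjusted p = 3.71e-06, and 0.0288 with an estimated correlation). Of 15 TGF-beta genes 2 were higher (5 adjusted over the list alone), Tgfbr1 by log2 1.63 (adjusted p = 1.14e-05; adjusted p = 0.0653 with an estimated correlation). Homing receptors were up (adjusted p = 0.00163; adjusted p = 0.12 with an estimated correlation), with Fut7 higher by log2 1.46. Inhibitory receptors (0.0229; adjusted p = 0.12 with an estimated correlation), costimulatory genes (0.0208; adjusted p = 0.375 with an estimated correlation) and lung stroma markers (0.0157; adjusted p = 0.0613 with an estimated correlation) were down, and erythroid markers up (0.0402; adjusted p = 0.548 with an estimated correlation). The Th9 list (15 measured, 3 up and 1 down, 6 adjusted over the list alone) was not called at adjusted p = 0.509, nor was the Th2 list (adjusted p = 0.646), whose median of -0.01 and mean of -0.12 lay opposite to its test. In all 413 genes differed (226 higher, 187 lower in Th9), 233 without Th2 replicate 1, 217 without Th9 replicate 1, 219 without Th2 replicate 2 and 195 without Th9 replicate 2. Against iTreg cultures 93 genes differed (43 and 50), with Batf (69 ± 17.6 against 17.7 RPKM, adjusted p = 0.00173) and Gata3 (adjusted p = 0.0315) higher in Th9 and Maf lower. Il9 (1027 against 168 RPKM, adjusted p = 0.255) and Foxp3 (11.6 against 50.6, adjusted p = 0.061) were not called. The Il9 libraries compared stood at 983 and 1070 RPKM in Th9 and 179 and 157 in iTreg cultures. The spread behind the test was pooled over all OT-II cultures, including Th17 vehicle libraries of different runs at 120 and 3.4 RPKM. The Th9 list was higher than in iTreg cultures (0.00351; adjusted p = 0.364 with an estimated correlation). Against iTreg the count was 14 without Th9 replicate 1, 28 without Th9 replicate 2, 25 without iTreg replicate 1 and 21 without iTreg replicate 2.

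The knockout asks what RARα does in Th9 cells without added RA. Rara itself stood at 6.63, 6.40 and 4.44 RPKM in the knockout libraries and at 7.83, 7.88 and 5.59 in the floxed libraries (5.82 ± 1.2 against 7.1 ± 1.31, adjusted p = 0.792). It was called only with pairing by replicate and quantile normalization together, a fit chosen after seeing the data (adjusted p = 0.0296). A gene total does not show a deleted exon, so the deletion could not be checked. Il9 rose from 487 ± 83.9 to 1138 ± 295 RPKM (n = 3 per group, log2 1.21, SE 0.21, adjusted p = 3.13e-06). Il13 rose from 3.21 ± 1.47 to 22.9 ± 14.8 RPKM (log2 2.39, adjusted p = 1.98e-14) and Il5 from 1.97 ± 0.447 to 6.83 ± 1.68 (log2 1.39, adjusted p = 5.33e-05). Other cytokine genes rose too: Il2 (log2 2.49), Il17f (log2 2.22), the chemokines Ccl4 (log2 2.07) and Ccl17 (log2 1.96), Tnfsf11 (log2 1.91) and Tnfsf4, which encodes OX40 ligand (log2 1.37). Penk, the enkephalin precursor, rose by log2 2.20, the Schlafen gene Slfn2 by log2 1.94, the receptor gene Klra3 by log2 1.93, and Crabp2, an RA-binding protein, by log2 1.57. Batf, which Th9 cells need for Il9, rose from 33.6 ± 3.41 to 71.2 ± 20.8 RPKM (log2 1.03, adjusted p = 0.00737). Igsf23 (log2 -1.51), Fam71f2 (log2 -1.37), Espn (log2 -1.35), Fam183b (log2 -1.33) and the kinase gene Matk (log2 -1.22) fell. Il4 (3.69 ± 0.478 to 7.27 ± 3.08 RPKM, adjusted p = 0.134), Foxp3 (5.02 ± 2.31 to 2.98 ± 0.872, adjusted p = 0.328) and Il10 (adjusted p = 0.121) were called only with libraries paired by replicate, at adjusted p of 3.84e-07, 0.000212 and 2.98e-06. Gata3 (0.812) and Irf4 (0.681) were not called, and Ifng, Il17a, Il17rb, Il1rl1, Pparg, Spi1 and Ccr9 were below the filter.

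Of 11 measured Th9 genes 3 rose in the knockout (adjusted p = 0.00127), of 10 Th2 genes 2 (0.00127), of 8 Th1 genes 2 (2.3e-05) and of 7 Th17 genes 2 (6.42e-07). None of these calls held with an estimated correlation (adjusted p = 0.969, 0.969, 0.751 and 0.751 with an estimated correlation), and with quantile normalization only the Th17 list passed (0.0316). Cholesterol synthesis was up at adjusted p = 0.049 (adjusted p = 0.969 with an estimated correlation). The Treg list (14, 0 up and 1 down, adjusted p = 0.338) and the retinoic acid response (10, Crabp2 called, adjusted p = 0.933, median -0.15 and mean 0.09) were not called. In all 218 of 10396 genes passed limma (129 up, 89 down), 2996 with libraries paired by replicate (1957 up, 1039 down), 1391 with quantile normalization and 0 with no filter on low values (2023 at an unadjusted p under 0.05), where Il9 had an adjusted p of 0.413. The count was 65 without floxed replicate 1, 56 without floxed replicate 2, 83 without floxed replicate 3, 57 without knockout replicate 1, 83 without knockout replicate 2 and 428 without knockout replicate 3. The other genes named as changed kept their calls in all 6 of these fits, except Batf (adjusted p = 0.0952, 0.101 and 0.201 without floxed replicates 1, 2 and 3, and 0.11 without knockout replicate 1).

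**Figure D2:**
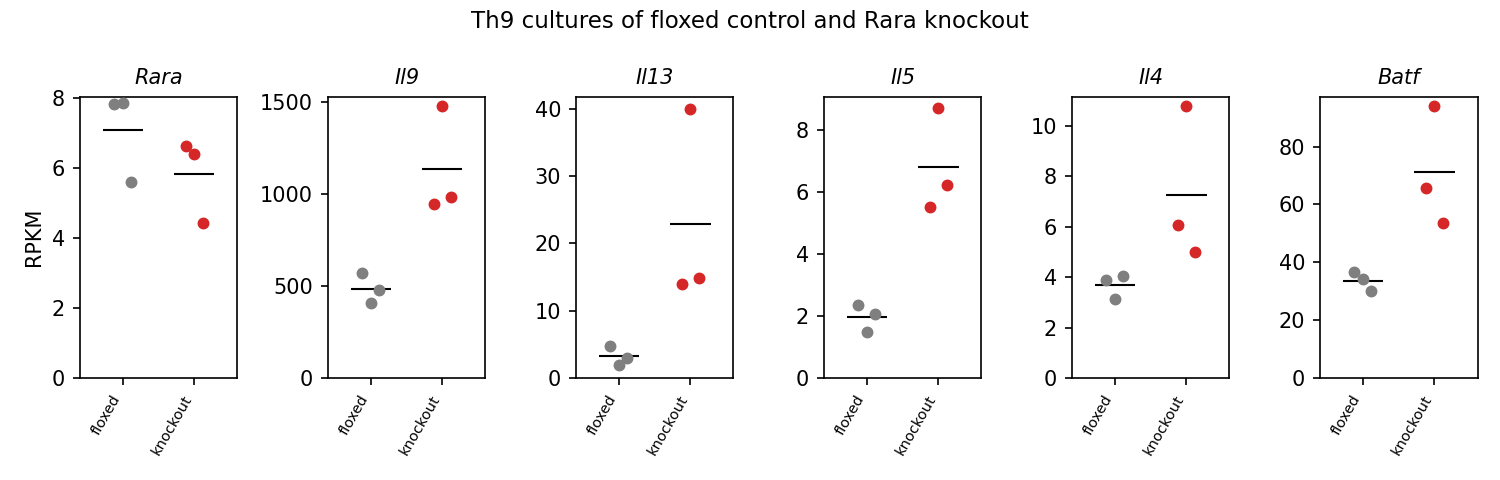
RPKM (linear axis) of 6 genes in Th9 cultures from floxed control (grey) and Rara knockout (red) mice; points are libraries and bars are means of 3. Il9 averaged 487 RPKM in floxed and 1138 in knockout cultures, while Rara averaged 7.1 and 5.82.

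Genes that respond to RA in wild-type Th9 cultures were then followed in the knockout libraries, which played no part in choosing them. Of the 138 genes lowered by RA at a log2 size of at least 1, 120 were measured in the knockout, with 60 up and 60 down (n = 120 genes, camera of limma, p = 0.499). The measured RA-raised genes were likewise not called (n = 124 genes, camera of limma, p = 0.229). Of the 199 genes lowered by RA at any size and tested in both comparisons, 7 rose in the knockout (2.5 expected) and 3 fell (1.7 expected), and of the 273 raised 7 rose as well (3.5 expected) and 2 fell (2.3 expected).

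Sorted lung cells show how far the reporter-marked population differs from other helper cells after papain. Against Th2 cells, no type 2 cytokine gene was called in YFP-positive Th9 cells. Il9 stood at 167 ± 130 against 294 ± 132 RPKM (n = 3, log2 -1.10, adjusted p = 0.353) and Il5 at a mean of 366 against 296 RPKM (log2 0.32, adjusted p = 0.728). Il13 stood at 647 ± 181 against 655 ± 256 (0.99) and Il4 at 150 ± 78.8 against 121 ± 16.6 (0.837). Il10 (0.758), Gata3 (0.901), Pparg (0.821), Il1rl1, the receptor for interleukin 33 (0.977), Il17rb (0.268), Rara (0.174), Irf4 (0.356), Batf (0.377), Ifng (0.186) and Il17a (0.794) were not called either. Foxp3 was lower, at 2.48 ± 1.11 against 22.2 ± 12.4 RPKM (log2 -2.65, adjusted p = 0.0101). Also lower were Izumo1r, a folate receptor of regulatory T cells (log2 -1.97), Nsg2 (log2 -3.14), Dynlt1f (log2 -2.88) and Art2b (log2 -2.50). Of 15 Treg genes 3 were lower (list adjusted p = 0.00126; adjusted p = 0.495 with an estimated correlation). Higher were Ccl7 (45.8 ± 26.5 against 0.125 ± 0.191 RPKM, log2 5.16) and Ccl24 (log2 4.67), chemokines, Wfdc17 (log2 4.57), the antibody receptor Fcgr2b (log2 4.54) and the antigen-presentation gene H2-Aa (log2 4.51). So were Mgp (log2 4.50), Tmem220 (log2 5.42), Tmem176a (log2 1.86) and Spi1, the transcription factor PU.1 (8.89 ± 1.76 against 0.723 ± 0.367 RPKM, log2 2.53, adjusted p = 0.0112).

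Markers of other cell types moved with the YFP-positive libraries. Of 13 myeloid genes 11 were higher than in Th2 cells (13 adjusted over the list alone, median log2 3.39, adjusted p = 2.15e-17; adjusted p = 0.32 with an estimated correlation). Lyz2, lysozyme, stood at 74.1, 123 and 281 RPKM in the YFP-positive and 6.62, 17.3 and 7.45 in the Th2 libraries. A YFP-negative library, Th17 replicate 2, also lay above Th2 replicate 2, by a median log2 of 2.67 for myeloid, 2.02 for erythroid and 1.36 for B cell markers, where YFP-positive replicate 2 lay above it by 2.52, 3.8 and 1.2. B cell (8 measured, 3 higher, 1.82e-06; adjusted p = 0.373 with an estimated correlation), lung stroma (12, 1 higher, 7 adjusted over the list alone, 0.000114; adjusted p = 0.416 with an estimated correlation), erythroid (4, 2 higher, 0.000208; adjusted p = 0.373 with an estimated correlation) and granulocyte and mast cell markers (4, none, 2 adjusted over the list alone, 0.0059; adjusted p = 0.416 with an estimated correlation) were also up. CD8 and NK markers were not (9, none, adjusted p = 0.657), nor ILC2 markers (12, 2 higher, 0.0525). Of the genes called higher, 72.7% of 260 with a culture value lay under 1 RPKM in cultured Th9 cells, against 18.5% of 92 called lower and 19.2% of all 12092. Cell cycle genes (1 of 20 lower, 0.000208; adjusted p = 0.552 with an estimated correlation), naive and memory genes (3 lower, 0.0064; adjusted p = 0.422 with an estimated correlation), costimulatory genes (0.0031; adjusted p = 0.422 with an estimated correlation) and homing receptors (0.0185; adjusted p = 0.559 with an estimated correlation) were down. Immediate early genes (none of 16 called, 0.00556; adjusted p = 0.422 with an estimated correlation) and the Th1 list (0.0291; adjusted p = 0.422 with an estimated correlation) were up. The Th9 (16, 1 up and 1 down, 4 adjusted over the list alone, 0.453), Th2 (14, none, 0.753) and Th17 lists (0.986) were not called.

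In all 358 of 12408 genes passed limma (264 higher, 94 lower), 600 with libraries paired by replicate, 72 (33 higher, 39 lower) among genes present in cultured Th9 cells, and 530 (338 and 192) with quantile normalization. Replicate 1 of both groups came from another run than replicates 2 and 3. The main fit does not adjust for run, and pairing by replicate partly does. The count was 111, 116 and 89 without Th2 replicates 1, 2 and 3, and 762 and 537 without Th9 replicates 1 and 2. Without replicate 1 of both groups 745 genes passed and Il9 was lower in Th9 (log2 -2.06, adjusted p = 0.0399), as was Irf4 (0.0281). Without Th9 replicate 1 Rara was higher (0.0434), and without Th2 replicate 3 Foxp3 (0.0558) and Spi1 (0.0553) lost their calls.

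**Figure D3:**
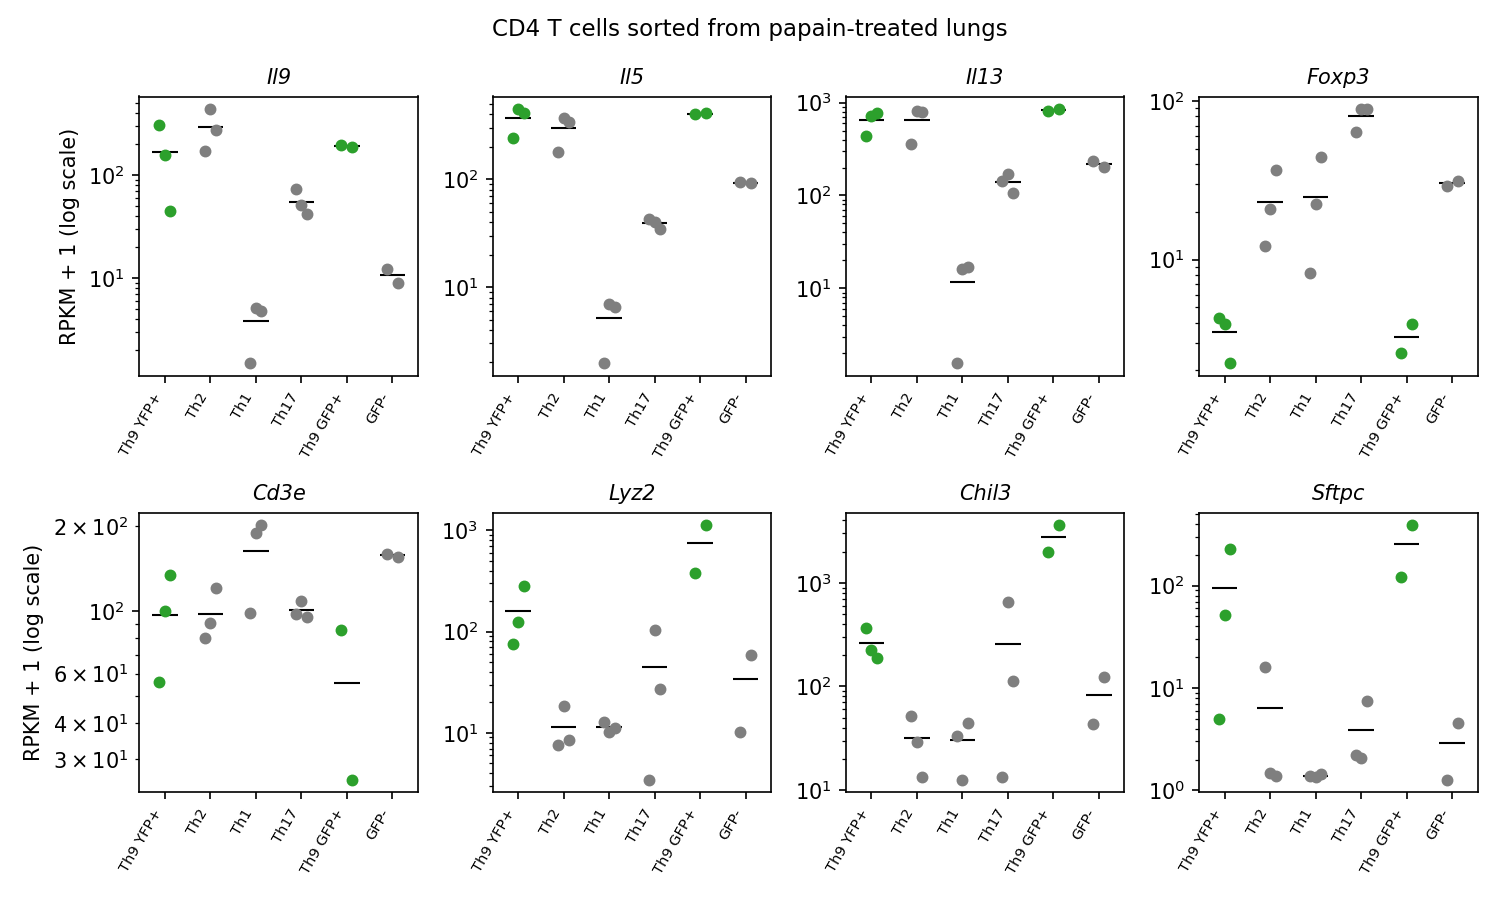
RPKM + 1 (log axis) of 8 genes in the 6 groups of sorted lung cells, with reporter-positive groups in green; points are libraries and bars are means. Il9 averaged 167 RPKM in YFP-positive Th9 and 294 in Th2 cells, and 189 in GFP-positive against 9.65 in GFP-negative cells.

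Against lung Th1 cells, YFP-positive cells had higher Il13 (647 ± 181 against 10.6 ± 8.71 RPKM, log2 6.38), Il5 (366 ± 110 against 4.17 ± 2.79, log2 6.31) and Il9 (167 ± 130 against 2.79 ± 2.01, log2 5.27, adjusted p = 2.91e-05). Il4 (log2 3.40), Pparg (log2 3.70), Il17rb (log2 3.27), Il1rl1 (log2 3.24), Il10 (log2 2.62), Irf4 (log2 2.20), Gata3 (log2 1.57), Rara (log2 1.17, adjusted p = 0.0286) and Crabp2 (log2 6.16) were higher too. The gate gene Cxcr3 (log2 -4.76), Ccr9 (log2 -2.85), Foxp3 (log2 -2.59), Ifng (log2 -1.81, adjusted p = 0.0479) and Stat4, which signals for interleukin 12 (log2 -1.37), were lower. The Th2 list (9 up, 1 down, 2.39e-06; adjusted p = 0.0808 with an estimated correlation), the Th9 list (9 up, 1 down, 7.74e-05; adjusted p = 0.218 with an estimated correlation) and myeloid markers (13 of 13 up, 4.49e-07; adjusted p = 0.298 with an estimated correlation) were higher. The Th1 list (10 down, 6.52e-06; adjusted p = 0.0961 with an estimated correlation) and interferon response (7 down, 1.13e-05; adjusted p = 0.387 with an estimated correlation) were lower. In all 2261 genes differed (1537 higher, 724 lower), but quantile normalization, which moved the median of all genes from 0.12 to -0.04, gave 1341 higher and 1615 lower. Without Th1 replicate 2 the count was 1335 and without replicate 3 of Th1 it was 1504.

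Against lung Th17 cells, Il5 (366 ± 110 against 38.3 ± 4.06 RPKM, log2 3.18), Il4 (log2 2.59), Il17rb (log2 1.04) and Spi1 (log2 2.12) were higher in YFP-positive cells, whereas Il9 (167 ± 130 against 54.2 ± 15.6, adjusted p = 0.25) and Il13 (adjusted p = 0.0692) were not called. Foxp3 (2.48 ± 1.11 against 79.2 ± 14.6 RPKM, log2 -4.57), the gate gene Ccr6 (log2 -3.58), Ikzf2, the Treg factor Helios (log2 -3.55), Il17a (log2 -3.30, adjusted p = 0.0428), Il23r (log2 -1.97) and Ctla4 (log2 -1.61) were lower. The Th17 list (8 down, 7.48e-12, and 0.0347 with an estimated correlation) and Treg list (7 down, 2.85e-09; adjusted p = 0.282 with an estimated correlation) were lower, and myeloid markers higher (3 called, 12 adjusted over the list alone, 2.58e-10; adjusted p = 0.282 with an estimated correlation). In all 454 genes differed (218 and 236), 177 among genes present in cultured Th9 cells, 208 without Th17 replicate 1, 111 without Th17 replicate 3, 873 without Th9 replicate 1 and 971 without replicate 1 of both groups.

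The GFP sorts ask what sets reporter-positive lung Th9 cells apart from reporter-negative cells. Il9 stood at 189 ± 7.34 RPKM in GFP-positive and 9.65 ± 2.31 in GFP-negative cells (n = 2, log2 4.18, SE 0.70, adjusted p = 0.00142). The labels name these groups Th9 and non-Th9 by the reporter, so the Il9 difference may have been set by the sort. Il5 stood at 407 ± 7.76 against 92.2 ± 1.9 (log2 2.13, adjusted p = 0.00671) and Il10 was higher by log2 1.88 (adjusted p = 0.0129). Batf3 (log2 3.58), Spi1 (18.9 ± 13.2 against 0.707 ± 0.418 RPKM, log2 3.39) and Tyms, thymidylate synthase (log2 2.01), were higher. Foxp3 (2.23 ± 0.946 against 29.3 ± 1.44 RPKM, log2 -3.26, adjusted p = 0.00249), the costimulatory receptor Cd27 (log2 -4.03), Tcf7, a factor of naive and memory T cells (log2 -3.36), and Slamf6 (log2 -3.21) were lower. So were Gimap7 (log2 -3.42), Il7r (log2 -2.27), Stat4 (log2 -1.95) and Il2rb (log2 -1.57). Ccr9 was lower as well (log2 -1.78). The T cell genes looked at had a median log2 difference of -1.41, so a lower share of T cells stays open for decreases of about that size. Rara was at the threshold (29.8 ± 19.4 against 11.1 ± 3.04 RPKM, adjusted p = 0.0495). Several of these calls hung on 1 library. Il5 had an adjusted p of 0.051 without either GFP-negative library, Il10 0.0746 without GFP-positive replicate 2 and 0.135 without GFP-negative replicate 1, and Ccr9 0.0546 without GFP-negative replicate 2. Rara had 0.438 without GFP-positive replicate 1, 0.274 without GFP-negative replicate 1 and 0.0983 without GFP-negative replicate 2. Il13 (833 ± 21.7 against 216 ± 21.7 RPKM, adjusted p = 0.0798), Il4 (0.142), Pparg (0.0736), Il17rb (0.0522), Il1rl1 (0.492), Gata3 (0.757), Irf4 (0.74), Batf (0.63), Ifng (0.901) and Il17a (0.989) were not called.

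Of 13 myeloid genes 13 were higher in GFP-positive cells (median log2 4.62, adjusted p = 1.58e-12; adjusted p = 0.353 with an estimated correlation), with S100a9 (log2 6.53) and S100a8 (log2 5.78) among the largest changes. Chil3, a lectin of macrophages, stood at 2774 ± 1137 against 81.8 ± 56.2 RPKM. Tmem220 (log2 7.90) and Serpina1a (log2 7.31), of no list, rose more than S100a9. In GFP-positive replicates 1 and 2 they stood at 1006 and 129 RPKM and at 510 and 61.6 RPKM. S100a9, at 160 and 581 RPKM, was instead higher in replicate 2. Of 12 lung stroma genes 8 were higher (9 adjusted over the list alone, 8.98e-06), among them Cdh5 of endothelium (log2 3.39) and surfactant Sftpc (253 ± 188 against 1.9 ± 2.3 RPKM), and of 8 B cell genes 7 (8.98e-06). No list call of GFP-positive against GFP-negative cells held with an estimated correlation (adjusted p = 0.353 for these lists). Of 5 T cell genes looked at, Cd3e (log2 -1.76, adjusted p = 0.0161), Cd4 (log2 -1.41), Lck (log2 -1.29) and Thy1 (log2 -1.61) were lower and Cd3g (log2 -0.73, adjusted p = 0.0568) was not called, where in YFP-positive cells Cd3e did not differ from Th2 (log2 -0.08). The Th9 list was higher (16 measured, 5 up and 2 down, 9 adjusted over the list alone, 0.0245; adjusted p = 0.577 with an estimated correlation). Across GFP-positive replicates 1 and 2, Spi1 (9.59 and 28.25 RPKM) and Ccl17 (19 and 43.4) rose like the myeloid marker Tyrobp (85.6 and 273.5). Il9 (195 and 184) and Batf3 (20.4 and 12.65), also called in the list, did not. Spi1 stood at 0.0203 ± 0.0287 RPKM in cultured Th9 cells. Whether the list call reflects myeloid RNA was not tested. Homing receptors (9 down, 0.000706), cytokine receptors (9 down and 1 up, 0.0122) and naive and memory genes (6 down, 0.018) were lower. Higher were granulocyte and mast cell markers (3 of 4, 0.0013) and erythroid markers (0.0445, and 0.0659 with quantile normalization). Of the 264 genes higher in YFP-positive than Th2 cells 203 were also higher in GFP-positive cells (22.6 expected), and of the 94 lower ones 59 were also lower (14.9 expected). The libraries compared differ between these tests but share 1 fitted spread. In all 3029 genes passed (1062 higher, 1967 lower) around a median of all genes of -0.31 (-0.15 with quantile normalization, which gave 1429 and 1980), and 2036 (335 and 1701) passed among genes present in cultured Th9 cells. The count was 1816 without GFP-positive replicate 2, 812 without GFP-negative replicate 1 and 943 without GFP-negative replicate 2. Without GFP-negative replicate 1, Chil3 (0.0735) and Sftpc (0.0587) lost their calls.

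Chromatin was compared to see where RA and RARα alter open and marked regions of Th9 cells. Over wild-type and floxed cultures together (4 RA and 4 vehicle libraries per mark), 1265 of 72927 regions of H3K4me1, a mark of enhancers, were gained or lost with RA, 789 of them lost. H3K27ac, a mark of active enhancers and promoters, was gained at 184 and lost at 29 of 45571 regions, open chromatin at 117 and 143 of 98502, and the promoter mark H3K4me3 at 8 and 10 of 26823. ATAC regions gained included 2:61893695-61894768, 8:26575737-26576683 and 12:40620371-40621463, and those lost 5:90241308-90242567 and 18:39309832-39310949. Of the 143 lost ATAC regions 24 (16.8%) also lost H3K4me1, against 0.1% of ATAC regions present in all libraries. Of the 117 gained ATAC regions 6 (5.13%) also gained H3K4me1, against 0.08%. The regions present in all libraries could show few such changes, because 72.6% of them overlap H3K4me1 present in all libraries. Other variable ATAC regions were not compared. Of the gained ones 82.9% held H3K4me1 in at least 1 library, below the 94.7% of ATAC regions present in all libraries. Within wild-type or floxed cultures alone (2 RA and 2 vehicle libraries) the counts were larger, but the wild-type histone libraries of replicate 1 with RA and with vehicle came from different runs. H3K4me1 then had 5808 regions gained and 1966 lost in wild-type and 996 and 5014 in floxed cultures, H3K27ac 2467 and 381 against 1157 and 1163. ATAC had 6981 and 1705 against 510 and 2457, and H3K4me3 137 and 57 against 183 and 467.

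In the knockout (4 libraries, both treatments, against 4 floxed), 9 H3K27ac regions were gained and 128 lost, 16 H3K4me1 regions gained and 250 lost, 209 ATAC regions gained and 84 lost, and 7 H3K4me3 regions gained and 34 lost (16 and 16 with the same number of peaks in each library). The direction differed between treatments for ATAC, with 1053 regions gained and 2852 lost with vehicle only but 2249 and 581 with RA only, and for H3K4me3 (46 and 402 against 501 and 302). H3K27ac had 298 and 1389 with vehicle and 530 and 2125 with RA, and H3K4me1 531 and 2359 against 1876 and 2342. Leaving out floxed RA replicate 2, the ATAC library with the fewest peaks, gave 212 gained and 672 lost ATAC regions in the knockout, and 858 gained and 146 lost with RA. Every such total rises when a library is left out, because fewer libraries have to line up. For the other marks the largest totals with RA were 2464 H3K4me1 and 548 H3K27ac regions without floxed RA replicate 1, and 147 H3K4me3 regions without wild-type vehicle replicate 1. In the knockout they were 697 H3K4me1 regions without floxed RA replicate 1, 618 H3K27ac regions without floxed vehicle replicate 1 and 130 H3K4me3 regions without floxed vehicle replicate 2.

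The regions that RA changed in wild-type Th9 cultures were then scored in the floxed and knockout cultures, which were not used to choose them. Of the 1966 regions that lost H3K4me1, 80.3% held a peak in floxed cultures with vehicle (77.7 and 83) and 20.4% with RA (12.9 and 27.9), a change of -59.9 percentage points. In knockout cultures the same regions went from 72% (64 and 79.9) to 54.5% (50.8 and 58.1), a change of -17.5, and comparison regions, with a peak in 1 RA and 1 vehicle library of wild-type cultures, changed by -22.7 in floxed and -10.3 in knockout. Of the 5808 regions that gained H3K4me1, 43.2% held a peak in floxed cultures with vehicle and 61.5% with RA (43.5 and 79.5), and 32.4% and 29.9% in knockout cultures. For the 2467 regions that gained H3K27ac the shares were 22.9% and 40.5% (31.6 and 49.4) in floxed and 14.4% and 16.1% in knockout cultures. ATAC regions lost with RA changed by -25.9 in floxed and -2.49 in knockout cultures, where comparison regions changed by -12.3 and 3.47, and ATAC regions gained by -1.27 and 5.52, the floxed RA libraries standing at 61.2% and 26.7%. Without floxed RA replicate 2 the gained ATAC regions changed by 16 in floxed cultures, and without floxed RA replicate 1 by -18.5. With the same number of top peaks taken from each library, the gained ATAC regions changed by 11.1 in floxed and 2.77 in knockout cultures. H3K4me3 regions gained changed by 6.57 in floxed and 15 in knockout cultures, an order that turned with the same number of peaks in each library (22.1 and 10.2), and those lost by -22.8 and 7.02. The lost H3K4me3 set held only 57 regions, and H3K4me3 comparison regions changed by -4.56 in floxed and 5.13 in knockout cultures. Within 1 genotype, 2 libraries against 2 leave no exact test below 0.05. The difference between the genotypes was not tested. For lost H3K4me1 and lost H3K4me3 regions, all 4 differences between an RA and a vehicle library of floxed cultures lay below all 4 of knockout cultures, at every choice of peaks tried. For lost ATAC regions they did too, except with the upper 50% of peaks (-45.5 to -6.78 against -8.42 to 3.62). For lost H3K27ac regions the ranges overlapped at every choice (-38.3 to -2.63 against -13.9 to 10.5 with all peaks). For gained H3K4me1 and H3K27ac regions they overlapped too, except with the same number of peaks in each library (10.2 to 46 against -0.58 to 7.17, and 10.4 to 42.4 against 0.45 to 9.75). Gained H3K4me3 ranges likewise lay apart only at that setting (16.5 to 27.7 against 4.37 to 16).

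**Figure D4:**
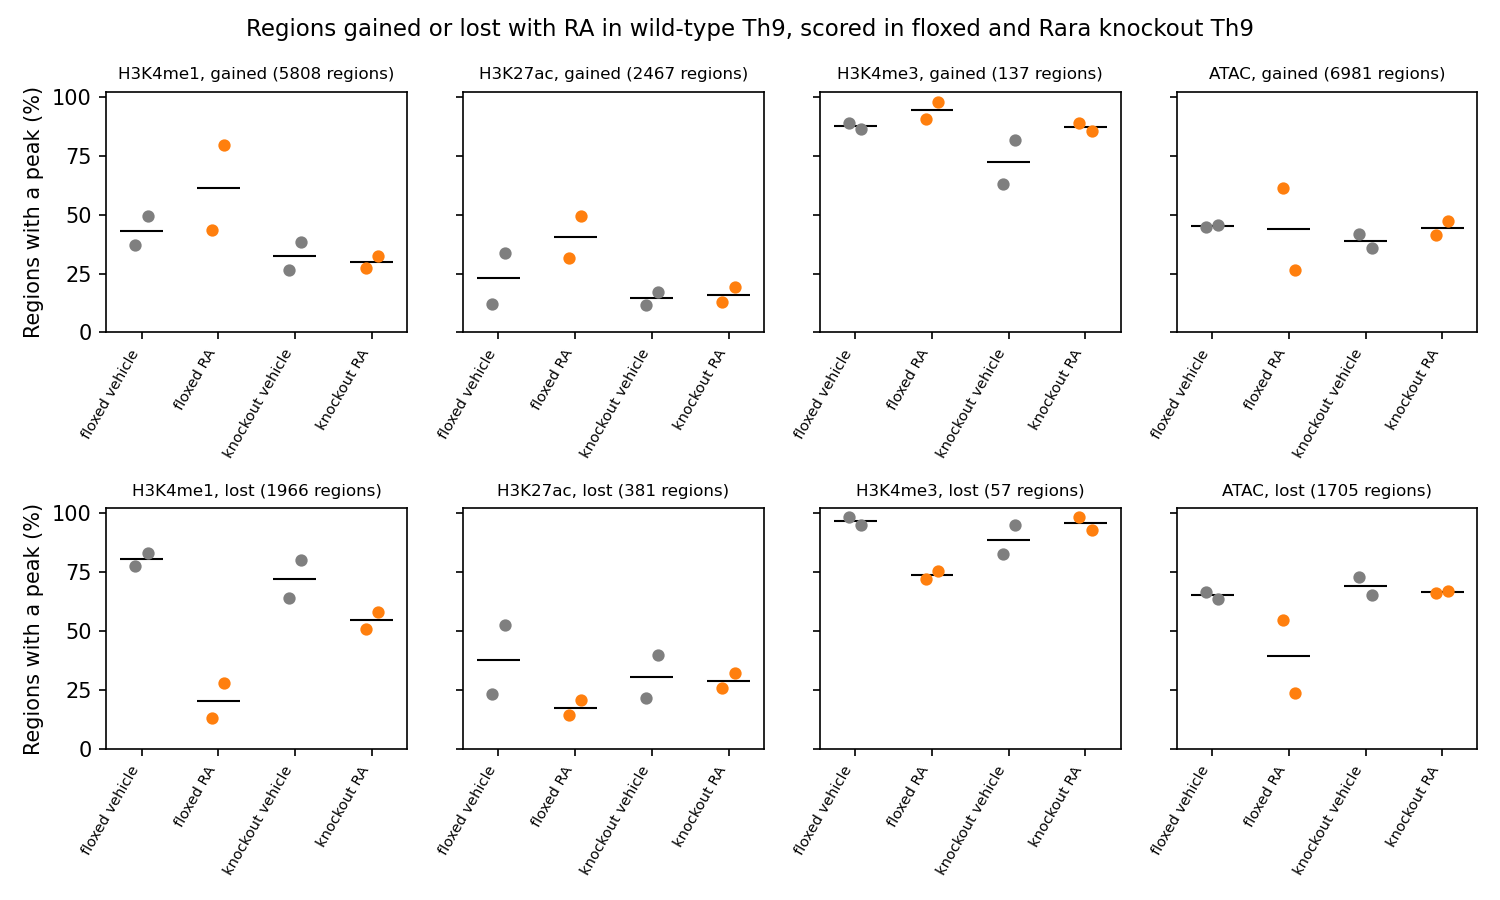
Percent of wild-type RA-gained or RA-lost regions with a peak in floxed and Rara knockout Th9 cultures with vehicle (grey) or RA (orange), for 4 assays; points are the 2 libraries and bars are means. Lost H3K4me1 regions went from 80.3% to 20.4% in floxed and from 72% to 54.5% in knockout cultures.

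Wild-type Th9 and Th2 cultures differed in open chromatin at 1797 gained and 8726 lost regions of 113138 (Th9 relative to Th2, 2 libraries each), or 2890 and 3433 with the same number of peaks in each library. Against iTreg cultures 3180 regions were gained and 2854 lost. Leaving out any 1 library raised these totals, because a group of 1 library is easier to separate, to between 21627 and 38848 against Th2 and between 15916 and 27893 against iTreg.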

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

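The tests of the lung marker and Scurfy patterns, and the use of equal peak numbers to weigh the floxed and knockout cultures, were chosen only after the result was seen. The equal peak number as a setting, the response specific to Th9 and the splits of libraries were planned. The myeloid markers of the YFP-positive lung libraries may come from RNA of myeloid cells in the sort: 11 of 13 list genes were called higher than in Th2 cells, and 13 of 13 in GFP-positive against GFP-negative cells. The most abundant of them, Chil3 and Lyz2, reached 367 and 281 RPKM in YFP-positive and 3579 and 1112 RPKM in GFP-positive libraries, although the sort took CD45.2+TCRb+CD44+CD4+ cells. Whether myeloid cells, free or attached to T cells, passed that gate was not tested. Of the 13 genes, 1 also reached 1 RPKM in cultured Th9 cells and 0 stand in another list. A difference between sequencing runs stays open. Replicate 1 libraries of 1 run showed a median myeloid log2 difference of 3.08 between YFP-positive and Th2 cells, 2.91 against Th1 and 3.66 against Th17 cells. That is 1 YFP-positive library, and against Th2 lung stroma (-0.43), granulocyte (-0.19) and B cell markers (0.25) hardly differed there. The YFP-negative Th17 replicate 2 library, with no reads of the further run that the other YFP-positive libraries hold, lay above Th2 by 2.67. In the GFP pattern (4.62) both positive libraries hold reads of a further run. The medians of CD8 and NK genes were -0.083 and -0.812. The sort for CD4+TCRb+ cells is meant to leave such cells out, so these medians cannot tell whether the share of T cells was lower. The T cell genes looked at had a median log2 difference of -0.08 between YFP-positive and Th2 cells. Between GFP-positive and GFP-negative cells it was -1.41, so a lower share of T cells stays open there.

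Scurfy and wild-type cultures differed at 0 to 11 genes by limma in every subset but Th1, which could mean that some Scurfy libraries held wild-type cells. In Th9 cultures with RA Foxp3 in replicate 1 was near the wild-type level (64 against 63.7 RPKM) and lower in replicate 2 (13.6). In other cultures with RA replicate 1 was well below wild type: 129 against 230 RPKM in iTreg and 0.422 against 8.33 RPKM in Th17. In iTreg cultures with RA the replicate 1 and replicate 2 differences from wild type correlated across genes at r = 0.36. That was the highest among the Th0, Th2, Th9 and iTreg cultures. In Th1 cultures with RA, where Foxp3 is close to absent, r was 0.405. Such a correlation can thus arise without Foxp3 and does not settle whether replicate 1 held Scurfy cells. In Th9 cultures with RA r was 0.146, which leaves the matter open. Loss of Foxp3 function acting where Foxp3 is transcribed most is another possible reading: among Th0, Th2, Th9 and iTreg cultures iTreg with RA had the most called genes (11). Over all subsets the counts did not follow Foxp3, because Th1 cultures with RA had 709 called genes (188 with quantile normalization) with Foxp3 at a mean of 0.0832 RPKM. Differences where Foxp3 is close to absent cannot tell whether its loss acts in iTreg cultures, so that reading stays open.

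Regions that gained H3K27ac or H3K4me1 with RA in wild-type cultures gained it in floxed but hardly in knockout cultures, which may reflect a need for RARα or different peak numbers between libraries. With the same number of peaks in each library the RA change was larger in floxed than in knockout cultures by 21.3 percentage points for H3K27ac and by 24.8 for H3K4me1. That setting also rechose the wild-type regions scored: 1344 instead of 2467 for H3K27ac and 4142 instead of 5808 for H3K4me1. The difference did not vanish with equal peak numbers, but the ranges of the genotypes overlapped at every other choice of peaks. Tags in peaks also ran from 6 to 17.1% over the H3K27ac libraries of the Rara cultures, so a cause in the libraries stays open. Each group holds 2 libraries, and the difference between the genotypes was not tested.

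One floxed ATAC library with RA (replicate 2) had 30200 peaks, far from the other 7 ATAC libraries of the Rara cultures (nearest 45477), a gap that chance gives in about 1 of 20 such groups, and 32 groups were searched. The RA response of Th9 cultures differed from the mean of Th0, Th2 and iTreg cultures at 50 genes, a difference between groups. In iTreg ATAC libraries with RA 53.9% of the 6981 regions gained with RA in Th9 cultures held a peak (50.3 and 57.5), against 32.6% with vehicle (23.8 and 41.3).

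The same libraries were also divided in every other way into groups of the same sizes. For comparisons of 3 against 3 there are 10 splits, too few for a share under 0.05: the knockout gave 218 genes (highest other split 56), and lung Th9 cells 358 against Th2 (0), 2261 against Th1 (285) and 454 against Th17 (28), so that in each case 1 of 10 splits, the real one, reached the count. For chromatin there are 35 splits, which move libraries freely between wild-type, floxed and knockout cultures and between replicates. They do not show whether RA or the genotype acts within 1 experiment, and splits balanced over wild-type and floxed cultures are too few for a share under 0.05. Over the free splits only the real one reached the count for H3K4me1 with RA (1265 regions, 1 of 35 splits as large, highest other 679). That is the smallest share 35 splits can give and was not adjusted over the marks and comparisons tried, so chance is not excluded. Other splits were as large for ATAC with RA (260, 9 of 35, highest other 1298) and in the knockout (293, 4 of 35, 571). So they were for H3K27ac with RA (213, 4 of 35, 795) and in the knockout (137, 4 of 35, 595). The same held for H3K4me1 in the knockout (266, 5 of 35, 473), and for H3K4me3 with RA (18, 8 of 35, 854) and in the knockout (41, 8 of 35, 121). Chance stays open for all of these. With the same number of peaks in each library only the real split reached the count for H3K4me1 with RA (1471, highest other 769) and for ATAC in the knockout (393, 237). The others still had splits as large: ATAC with RA (337, 2 of 35, 1774), H3K27ac (215, 2 of 35, 704; knockout 106, 4 of 35, 307), H3K4me1 in the knockout (248, 3 of 35) and H3K4me3 (44, 2 of 35, 168; knockout 32, 7 of 35, 65). The largest other split for H3K27ac and H3K4me3 with RA parted wild-type from floxed libraries, and for H3K27ac in the knockout it parted replicate 1 from replicate 2. Splits of several times the real count point to a structure of the samples by experiment and replicate. Within wild-type and within floxed cultures RA gave 2467 gained and 381 lost H3K27ac regions in wild-type and 1157 and 1163 in floxed cultures, and 137 and 57 against 183 and 467 for H3K4me3.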

How the results depend on the processing

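All settings below were planned except those named as chosen after seeing the data. Over 38 comparisons and 406 alternatives, 260 values stayed the same, 4 were weaker, 3 reversed and the others moved. A count was held to stay the same within 1.5 times, and a share of held-out regions within the combined SD of its libraries. Over 485 single genes, lists or shares and 4836 alternatives, 4083 stayed, 567 were weaker, 131 stronger, 45 moved and 10 reversed. Where no cause is given, the cause was not tested. A required overlap of at least 50% between peaks and no fold limit on held-out sets changed no result tried (14 and 4 results).

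A block for replicate number, the pairing of libraries with the same number, raised the counts of called genes. RA gave 1464 genes in Th9, 414 in Th0, 552 in Th1, 461 in Th2, 1585 in Th17, 2201 in iTreg and 1014 in Scurfy Th9 cultures, and 155 specific to Th9. Th9 cultures gave 1055 against Th2 and 502 against iTreg, the knockout 2996, and lung Th9 cells 600 against Th2 and 921 against Th17. Over the Scurfy and other secondary contrasts the total was 8745, against 2830 without the block. With it RA in Th9 cultures also lowered Batf (adjusted p = 0.000362), Gata3 (0.00594), Il4 (0.00787) and Il10 (0.0114). The pairing is borne out by the data for the knockout, for lung Th9 cells against Th2 and Th1, and for RA in Th17 cultures. In those lung groups and the Th17 cultures replicate number also marks a sequencing run. Pairing there is at least partly an adjustment for run. In the other OT-II cultures 2 pairs, with no label that says what the number marks, do not settle it: same-numbered Th9 libraries with and without RA correlated at r = 0.611. With quantile normalization the knockout gave 1391 genes and lung Th9 against Th17 715, and the lung gene set in the knockout had p = 0.0834 (n = 81 genes, camera of limma). Block and quantile normalization together, chosen after seeing the data, gave 3490 in the knockout. A pseudocount of 0.1 gave 60 genes for RA in Th1 cultures and 20 for the Th9-specific response. With no filter on low values RA in Th1 cultures gave 1075 genes, the knockout 0 (2023 at an unadjusted p under 0.05 in limma) and the secondary contrasts 8863. Fitted on the compared groups only, lung Th9 cells gave 126 genes against Th2, 951 against Th1 and 52 against Th17, with fewer libraries to estimate spread. Among genes present in cultured Th9 cells, chosen after seeing the data, they gave 72 against Th2 and 177 against Th17, with fewer genes tested. With an estimated correlation 2 of 41 list calls in 5 main comparisons held, and the lung gene set in the knockout had p = 0.245.

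Each library was left out in turn, and in the lung YFP comparisons also replicate 1 of both groups together (971 genes against Th17). Where an arm kept 1 library, limma pools the spread and the lone library is assumed to vary like the others. RA then gave 291 to 405 genes in Th9, 29 to 86 in Th0, 35 to 114 in Th1, 63 to 143 in Th2, 168 to 784 in Th17, 410 to 672 in iTreg and 123 to 359 in Scurfy Th9 cultures, and 21 to 50 specific to Th9. Scurfy against wild type gave 0 to 1 in Th9 (1 without Scurfy replicate 1), 0 to 1 in iTreg (1 without Scurfy replicate 1) and 0 to 1 for the difference of RA responses (1 without Scurfy RA replicate 1). Th9 cultures gave 195 to 233 against Th2 and 14 to 28 against iTreg, and the knockout 56 to 428 (428 without knockout replicate 3). Lung Th9 cells gave 89 to 762 against Th2, 1335 to 3294 against Th1 and 111 to 971 against Th17, GFP-positive cells 812 to 2093, and the secondary contrasts 2275 to 4258. The lung gene set in the knockout had p between 8.69e-05 and 0.927 (0.927 without knockout replicate 2).

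For peaks, leaving out a library must raise a count, because fewer libraries have to line up. With RA the range was 362 to 1004 regions for ATAC, 271 to 548 for H3K27ac, 1463 to 2464 for H3K4me1 and 19 to 147 for H3K4me3. In the knockout it was 369 to 884, 199 to 618, 373 to 697 and 61 to 130, and Th9 ATAC gave 21627 to 38848 against Th2 and 15916 to 27893 against iTreg. With the upper 50% of peaks ATAC gave 129 with RA, 173 in the knockout, 5477 against Th2 and 3195 against iTreg, H3K4me1 158 in the knockout, and H3K4me3 5 with RA and 2 in the knockout. With the same number of peaks in each library H3K4me3 gave 44 with RA and ATAC 6323 against Th2. In the held-out regions that setting turned gained ATAC in floxed cultures from -1.27 to 11.1 percentage points, gained H3K4me1 in the knockout from -2.45 to 3.3 and lost H3K4me3 in the knockout from 7.02 to -0.51, and raised gained H3K4me3 in floxed cultures from 6.57 to 22.1. Without single libraries gained ATAC in floxed cultures ran from -18.5 (without floxed RA replicate 1) to 16 (without floxed RA replicate 2), lost ATAC in the knockout from -6.45 to 1.47, gained and lost H3K27ac in the knockout from -1.42 to 4.74 and from -10.8 to 7.35, gained H3K4me1 in the knockout from -8.33 to 3.43 and gained H3K4me3 in floxed cultures from -0.05 to 10.2.

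Wild-type ATAC libraries had fewer filtered tags than those of the Rara cultures (1.7 M to 7.88 M against 16.2 M to 34.1 M) but more peaks (42903 to 89591 against 30200 to 58276) and more tags in peaks (31.4 to 48.1% against 12.9 to 34.2%). What depth does to the peak comparisons was not tested. RNA read depth is unknown.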

Other observations

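In iTreg cultures with RA, where Foxp3 was most abundant, 11 genes differed between Scurfy and wild type by limma. Runx3, a transcription factor of cytotoxic and Th1 cells, was higher in Scurfy cultures (log2 1.69, adjusted p = 0.0275, n = 2 per group). Higher too were the kinase gene Pim2 (log2 1.66), the neuropeptide receptor Vipr2, Gucy1a3, Tjp1, Ifit1bl1 (log2 1.23, adjusted p = 0.000162) and Plscr4 (log2 1.04, adjusted p = 1.68e-05). The neuropeptide galanin (Gal, log2 -1.63), Nfatc4 (log2 -1.22) and Ttyh1 were lower. Foxp3 stood at 229.9 and 155.2 RPKM in the wild-type and 128.5 and 46.9 in the Scurfy libraries. At an unadjusted p under 0.05 there were 528 genes. In Th1 cultures with RA, where Foxp3 is close to absent, 709 genes differed (140 higher and 569 lower in Scurfy), 188 with quantile normalization.

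Open chromatin of iTreg cultures changed with RA at 5387 gained and 1998 lost regions of 101353. Of the 1705 regions that lost accessibility with RA in Th9 cultures, 19.7% held a peak in iTreg cultures with RA and 35% with vehicle, and of 12351 comparison regions 41% and 35.8%. Th2 cultures with vehicle held a peak at 35.7% of the gained and 66.7% of the lost Th9 regions.

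The 257 genes at a log2 size of at least 1 above Th2 cells in lung Th9 cells were followed in the cultures. In the knockout 81 were measured, 36 higher and 45 lower, and the set moved down (n = 81 genes, median log2 -0.03, camera of limma, p = 0.00899, 0.245 with an estimated correlation, 0.0834 with quantile normalization, 0.146 without floxed replicate 3 and 0.927 without knockout replicate 2). With RA in Th9 cultures 152 were measured, 93 higher and 59 lower (n = 152 genes, camera of limma, p = 0.729). Of the genes higher in cultured Th9 than Th2 cells, 10 were higher in lung Th9 than lung Th2 cells (2.9 expected) and 10 were lower (1.6 expected).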
